A study of Mus musculus with 24 samples.

How the data were processed

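Liver RNA of male B6C3F1 mice given DEHP (1150 mg/kg/day, 10 ml/kg by oral gavage) or corn oil every 24 h for 3 days was hybridised to 24 Affymetrix arrays of 45101 probe sets, 3 arrays for each of 8 groups of compound and time (2, 8, 24 and 72 h). Per the labels, total RNA was biotin-labelled with the standard Affymetrix procedures. The deposited values are log2 signals that the authors computed with RMA, whose version the labels do not give. The deposited table ranges from 2.84 to 14.55, holds all 24 samples and no others, and was checked to be on that scale. No detection calls were used here, so signal over background was judged only by a filter on dim genes.

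Probe sets were joined to gene symbols through the annotation table supplied with the series. Of 35890 annotated probe sets, 34958 carried 1 symbol and 932 several; 9211 probe sets had no annotation row. Each of 18194 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 9012 genes with more than 1 probe set. Probe sets without a single gene were tested apart from the genes. Some members of the gene lists have no annotated probe set and are not analysed here.

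Groups were taken from the sample labels alone. The design text names 6 mice, whose relation to the 3 arrays of a group is not stated. The RC numbers in the titles give replicate 1 of every group the numbers 1 to 8, and 2 of the 8 h arrays (corn oil replicate 3 and DEHP replicate 2) share the number 14. Over all probe sets these 2 arrays correlated with r = 0.99 and differed with an SD of 0.282, against 0.177 for the closest arrays, so they are not copies of the same values. Arrays have no sequencing depth, and precision rests on the number of arrays. With 3 arrays per group the linear model had 16 residual and 6.21 prior degrees of freedom.

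Gene tests used R 4.3.3 and limma 3.58.1, with 1 model of the 8 group means over all 24 arrays, empirical Bayes variances and moderated t tests of DEHP against corn oil at each time. An F test over the 4 contrasts asked for an effect at any time, a second F test and contrasts of successive times for a difference between times, and another F test for differences between times in corn oil. The p-values were adjusted by the Benjamini-Hochberg method over 18194 genes in each test, and genes with an adjusted p under 0.05 were called. Counts adjusted over a list alone used the p-values of its members only. Overlaps of called genes were tested with Fisher's exact test.

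Gene lists (37) were written by hand before the data were examined, as were the groups, the comparisons, the naming rule and most alternatives. The main lists covered peroxisomal oxidation, mitochondrial oxidation, omega-hydroxylation, drug-metabolism genes of CAR and PXR, DNA replication, and mitosis. Other lists covered ketone body synthesis, lipid uptake and droplets, fatty acid and cholesterol synthesis, bile acids, aryl hydrocarbon receptor genes, antioxidant defence, immediate-early genes, p53 targets, apoptosis, acute phase proteins, complement and coagulation, interferon response, the clock, glucose, amino acid catabolism, endoplasmic reticulum folding, heat shock, the proteasome, male-biased and female-biased genes, and growth hormone and IGF signalling. Markers of macrophages, endothelium, stellate cells, bile duct, lymphocytes, neutrophils, red blood cells, exocrine pancreas and adipocytes completed them. Each list was tested at each time with camera of limma, with a preset correlation of 0.01 between genes and with a correlation estimated from the arrays, and p-values were adjusted over 148 tests.

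Named genes followed a fixed rule. At each time it took the 8 largest rises and 8 largest falls among called genes whose 3 DEHP arrays all lay on one side of the 3 corn oil arrays. It took up to 4 called members of each list by size of change, or the member with the largest change where none was called. It also took fixed genes at every time (among them Ppara, Rxra, Cyp4a14, Ehhadh, Cpt1a, Pdk4, Fgf21, Cd36, Cyp7a1, Cyp2b10, Cyp1a1, Ccnd1, Mki67, Cdkn1a and Myc). Between times it took the 6 largest called differences of each sign, and in corn oil these and up to 8 clock genes. Unnamed and predicted genes were passed over. The rule covered 220 genes, of which the text names a part. Of 130 called values of genes with more than 1 probe set, 15 had a probe set of the other sign.

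The alternatives changed 1 choice at a time: the replicate number as a fixed or random block, the first replicates against the later ones as a block, genes above the 40th percentile of the mean signal, the mean of all probe sets of a gene, a variance trend with robust estimation, array weights, median centring, quantile normalization, an adjusted p under 0.01, an added 1.5-fold threshold, leaving out both arrays numbered 14, leaving out each array in turn, and the 6 arrays of a time alone. After the data were seen, 3 more were added for all results (the Actb 3' minus 5' difference as a covariate, the mean of the pancreas markers as a covariate, and leaving out both corn oil 8 h replicate 2 and corn oil 72 h replicate 1), and quantile normalization was extended to the lists and leaving out each corn oil array to the lists between corn oil times. Comparisons of the real grouping with other groupings used all 10 splits of the 6 arrays of a time, or 100 groupings with the real one included.

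The test was tested on simulated data with the groups of this study. Of genes given a log2 change of 0.5, 62.7% to 65.7% were called, and of those given a change of 1, 94% to 100%. Between 5 and 10 of the unchanged genes were called at each time. A list shifted by 0.3 was called at all 4 times, with 0 of 144 tests of other lists called. The simulated genes varied independently of each other. The simulation therefore does not show how often the preset correlation calls lists whose genes vary together. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The labels of the arrays do not state separate animals, a processing date or the hour of sampling, so no batch or time of day entered the model.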

Results

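Messenger RNA was measured in the liver of male B6C3F1 mice on 24 Affymetrix arrays of 45101 probe sets each. The mice received diethylhexylphthalate (DEHP), a plasticiser and peroxisome proliferator that the study's title names a rodent non-genotoxic carcinogen, at 1150 mg/kg/day by oral gavage, or the corn oil vehicle alone. Doses were given every 24 h for 3 days, and liver was sampled at 2, 8, 24 and 72 h. Each of the 8 groups of compound and time held 3 arrays. The labels do not say whether the arrays of a group came from separate animals, so every p-value measures the spread between these samples. The design text names 6 mice without saying what that number covers, and it does not say how many doses preceded the 24 h and 72 h samples. Arrays give no read depth, and their number limits the precision. The median log2 signal of an array lay between 6.46 and 6.55, and arrays of the same group correlated with r between 0.989 and 0.996 across probe sets, which are not independent replicates. Changes below are log2 differences between DEHP and corn oil of the same time ± SE from the fit, with n = 3 arrays in each group and p-values adjusted over 18194 genes.

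Some arrays stood apart from their group. Corn oil 8 h replicate 2 had the largest difference between the 3' and 5' probe sets of Actb, a sign of RNA degradation, at 1.46 against 0.81 for the next array. Its 18S ribosomal RNA signal was also the highest, at 12.35 against 11.08. Corn oil 72 h replicate 1 had high means of the immediate-early genes (1.31 above the mean over all arrays), the acute phase genes (1.11) and the neutrophil markers (0.53). Exocrine pancreas markers, which a liver piece can carry from neighbouring tissue, were high in DEHP 2 h replicate 1 (3.30), corn oil 72 h replicate 1 (2.05), corn oil 2 h replicate 2 (1.81) and DEHP 72 h replicate 1 (1.47).

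**Figure D1:**
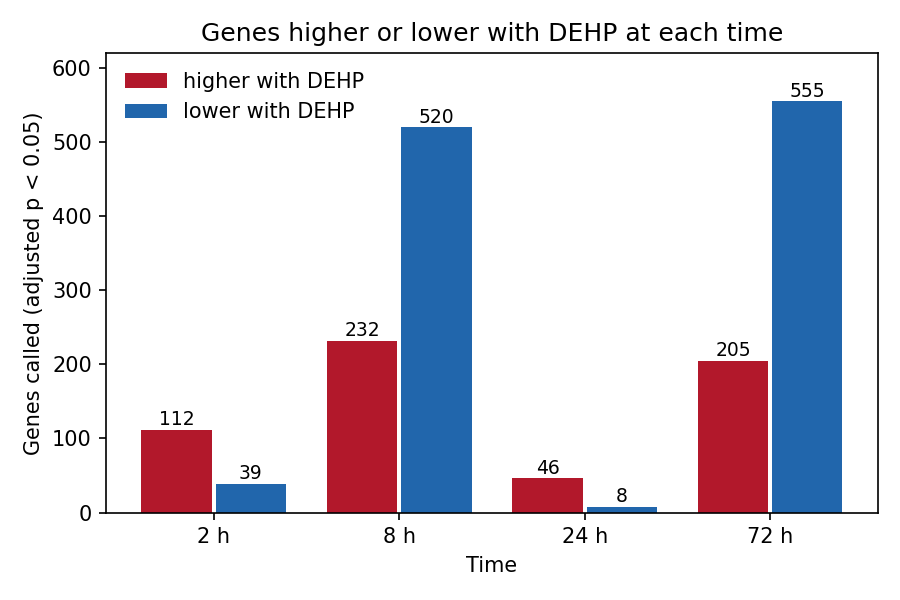
Number of genes (vertical axis) called higher or lower with DEHP than with corn oil at each time, at an adjusted p under 0.05 with 3 arrays in each group. Lower genes outnumbered higher ones at 8 h (520 against 232) and at 72 h (555 against 205), and higher ones outnumbered lower ones at 2 h (112 against 39) and at 24 h (46 against 8).

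The 2 h samples address the earliest sampled response of the liver to the compound. Genes of fatty acid use were among the largest rises. Pdk4, a kinase that switches off pyruvate dehydrogenase and so spares glucose, rose by 4.96 ± 0.27 (adjusted p = 1.47e-10), from 7.09 ± 0.33 to 12.05 ± 0.08 (mean and SD, n = 3 arrays). Cyp4a14, a microsomal omega-hydroxylase of fatty acids, rose by 4.44 ± 0.40 (adjusted p = 1.19e-06), and Acot1, a thioesterase that splits acyl-CoA, by 3.25 ± 0.43 (adjusted p = 0.000123). Ehhadh, a bifunctional enzyme of peroxisomal beta-oxidation, rose by 1.93 ± 0.21 (adjusted p = 1.47e-05). Cdkn1a, a p53 target that restrains the cell cycle, rose by 1.81 ± 0.21 (adjusted p = 3.35e-05).

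Outside fatty acid oxidation, the 2 h rises included G0s2, an inhibitor of triglyceride breakdown (2.39 ± 0.36), Gadd45b, a stress response gene (2.33 ± 0.32), Vnn1, a pantetheinase (2.04 ± 0.30), and Rab30, a small GTPase (2.00 ± 0.26). Saa2, an acute phase protein, rose by 4.21 ± 0.95 (adjusted p = 0.0344), and its call held only without DEHP replicate 2, with changes from 3.75 to 5.00 over the 6 fits that left out 1 array. Among the falls, Foxo3, a transcription factor of fasting and stress, changed by -0.93 ± 0.14 (adjusted p = 0.000649) and the transcriptional regulator Hes6 by -1.08 ± 0.19, a call lost without DEHP replicate 3 (-1.22 to -0.93 over the 6 fits). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.40 ± 0.29 (adjusted p = 0.0195), a call lost without corn oil replicate 2 or 3 or DEHP replicate 2 or 3 (-1.66 to -1.17 over the 6 fits). Acss2, which makes acetyl-CoA from acetate, fell by 1.45 ± 0.31, a call lost without corn oil replicate 1 or 3 or DEHP replicate 1 or 3 (-1.94 to -1.16). Zfp385b also fell (-1.08), though 1 of its 3 probe sets was at 0.01. Values of genes fixed for every time but not called were -0.02 for Ppara, the receptor through which peroxisome proliferators act, 0.97 for Cyp2b10, a drug-metabolising enzyme (adjusted p = 0.188), and -0.11 for Mki67, a marker of dividing cells.

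Grouped by the fixed lists, 8 of 33 measured genes of peroxisomal oxidation rose at 2 h and 0 fell (16 and 1 adjusted over the list alone), with a list median of 0.23 (camera adjusted p = 5.77e-14). Pex11a, a factor of peroxisome division (0.96 ± 0.17), and Pxmp4, a peroxisomal membrane protein (0.99 ± 0.15), were among them. Of 21 mitochondrial oxidation genes 4 rose (10 adjusted over the list alone; median 0.24, adjusted p = 3.64e-10), including the carnitine transporter Slc22a5 (1.66 ± 0.19). Omega-hydroxylation (2 of 9 rose; 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.000473) and ketone body synthesis (2 of 5, likewise 2 adjusted over the list alone; adjusted p = 0.00171) also went up. So did lipid uptake and droplets (4 of 23 rose, 8 adjusted over the list alone; median 0.15, adjusted p = 2.8e-07), with Plin2, a lipid droplet coat protein, at 0.93 ± 0.12. With an estimated correlation the adjusted p of these 5 lists was 0.0608, 0.165, 0.0582, 0.0744 and 0.0744. The lipid uptake median was 0.23 without DEHP replicate 3, and the omega-hydroxylation median (0.09) was 0.18 without corn oil replicate 3. The ketone body median (0.06) was 0.15, 0.01 and 0.03 without corn oil replicate 1, 2 or 3, and 0.10 and 0.11 without DEHP replicate 1 or 3.

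Fatty acid and triglyceride synthesis went the other way at 2 h. Of its 20 genes 19 had negative values (median -0.91, adjusted p = 8e-12), with 0 called over all genes and 12 lower adjusted over the list alone; Acly, which makes cytosolic acetyl-CoA, was at -1.33 (adjusted p = 0.0733). Cholesterol synthesis also shifted down (median -0.34, adjusted p = 2.3e-07; 0 of 20 called, 7 lower adjusted over the list alone). Under the estimated correlation the adjusted p was 0.125 and 0.305. The list means of fatty acid synthesis were -0.46, 0.32 and -0.26 on the 3 DEHP arrays against 0.54, 0.38 and 0.68 on the corn oil arrays. DEHP replicate 2 thus lay close to corn oil replicate 2. Acute phase genes shifted up (median 0.37, mean 1.04, adjusted p = 1.14e-16), with 3 of 25 called higher and 10 adjusted over the list alone. That list's adjusted p was 0.107 with an estimated correlation, and its median was 0.56 without DEHP replicate 2. The list means of acute phase genes were 1.18, 0.04 and 0.90 on the 3 DEHP arrays against -0.45, -0.42 and -0.13 on the corn oil arrays, and the pancreas markers were highest on the first of these DEHP arrays.

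Smaller downward shifts at 2 h covered amino acid catabolism (median -0.17, adjusted p = 8.84e-06; 1 of 25 lower, 8 adjusted over the list alone), where Prodh, the first enzyme of proline breakdown, fell by 0.84 (a call held in 2 of the 6 fits without 1 array), and heat shock proteins (-0.24, adjusted p = 0.000285; 0 of 13 called, 2 lower adjusted over the list alone). Stellate cell markers (median -0.20, adjusted p = 0.00148), clock genes (-0.25, adjusted p = 0.007; 1 of 21 lower), DNA replication genes (-0.08, adjusted p = 0.0139; 1 of 34 lower) and aryl hydrocarbon receptor genes (-0.20, adjusted p = 0.019) followed. Adjusted over the list alone, these last 4 lists held 0, 7, 1 and 0 lower genes, and the clock list 1 higher gene. The p53 targets shifted up (0.06, adjusted p = 0.0101; 1 of 17 higher, and 1 adjusted over the list alone). The adjusted p with an estimated correlation was 0.158 for amino acid catabolism, 0.218 for heat shock, 0.36 for stellate cell markers, 0.101 for clock, 0.42 for DNA replication, 0.147 for aryl hydrocarbon receptor genes and 0.0868 for p53 targets. Leaving out 1 array ended the call of the clock list (corn oil replicate 3, adjusted p = 0.127; DEHP replicate 2, 0.0793), of the aryl hydrocarbon receptor and p53 lists (DEHP replicate 1, 0.0836 and 0.155) and of the stellate list (DEHP replicate 3, 0.0898). The p53 median was 0.10 without corn oil replicate 1 and 0.11 without DEHP replicate 2. In the DNA replication list the call also ended with the mean of all probe sets (adjusted p = 0.0687) and with genes above the 40th percentile (0.0724), and the p53 call ended with the latter too (0.0528).

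In all, 151 of 18194 genes were called at 2 h, 112 higher and 39 lower, and 1533 had an unadjusted p under 0.05. At least 2-fold changes were 31 higher and 6 lower. Over all 18194 genes, called or not, 11.4% had all 3 DEHP arrays on one side of all 3 corn oil arrays, against 10% by chance. The count was 77 without corn oil replicate 1, 65 without corn oil replicate 3, 72 without DEHP replicate 1, 239 without DEHP replicate 2 and 69 without DEHP replicate 3, and 95 from the 6 arrays of that time alone. Of 39 called genes that the naming rule covers, 18 stayed called in each of the 6 fits without 1 array.

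At 8 h genes of fatty acid use were again raised, and the drug-metabolism gene Cyp2b10 was called. Pdk4 rose by 5.97 ± 0.27 (adjusted p = 2.91e-12). Cyp2b10, the classic target of the receptor CAR, rose by 5.13 ± 0.29 (adjusted p = 1.64e-10), from 6.55 ± 0.10 to 11.68 ± 0.71 (mean and SD, n = 3 arrays). Cyp4a14 rose by 3.92 ± 0.40, Acot1 by 3.43 ± 0.43, the peroxisomal thioesterase Acot3 by 3.33 ± 0.35 and Ehhadh by 2.79 ± 0.21. Falls were led by Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1 (-2.29 ± 0.25, adjusted p = 5.96e-06), and Hsd3b5, a steroid enzyme typical of male mouse liver (-1.96 ± 0.17, adjusted p = 3.34e-07).

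Further 8 h falls were those of Apol7a (-1.60 ± 0.12), Enho, which encodes the secreted peptide adropin (-1.54 ± 0.23), the constitutive serum amyloid Saa4 (-1.27 ± 0.26) and Etnppl, an enzyme of phosphoethanolamine breakdown (-1.22 ± 0.27). Of Enho, 1 of 4 probe sets was at 0.07. Rxra, the partner receptor of Ppara, fell by 0.38 ± 0.09, a call lost without corn oil replicate 1 or 2 or DEHP replicate 1 (-0.43 to -0.35 over the 6 fits), and its probe sets ranged from -0.38 to 0.21. Ppara itself was at -0.19 (adjusted p = 0.789). Among called genes the probe sets also differed in sign for Angptl4, Bid, Fads2, Hyou1 and Stat5b.

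Of the 33 peroxisomal oxidation genes, 12 rose and 1 fell at 8 h (18 and 1 adjusted over the list alone; median 0.28, adjusted p = 2.01e-19). The thioesterase Acot4 rose by 2.15 ± 0.21 and Pex11a by 1.40 ± 0.17. Mitochondrial oxidation had 11 of 21 higher (14 adjusted over the list alone; median 0.43, adjusted p = 2.01e-19), with the thioesterase Acot2 at 2.28 ± 0.24, and omega-hydroxylation 4 higher and 1 lower of 9 (the same adjusted over the list alone; adjusted p = 2.48e-05). Lipid uptake and droplets had 10 of 23 higher (11 adjusted over the list alone; median 0.47, adjusted p = 2.41e-14), including Plin5, which links lipid droplets to mitochondria (1.12 ± 0.21). With an estimated correlation the adjusted p was 0.0289 for peroxisomal oxidation, omega-hydroxylation and lipid uptake, and 0.0582 for mitochondrial oxidation. The omega-hydroxylation median was 0.27, and 0.41 without corn oil replicate 2.

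Drug-metabolism genes of the receptors CAR and PXR rose in 8 of 23 cases at 8 h (11 adjusted over the list alone; median 0.23, adjusted p = 1.66e-11), with Cyp2c55 at 1.70 ± 0.29 and Gadd45b at 2.29 ± 0.32 beside Cyp2b10. Heat shock genes rose in 4 of 13 cases (8 adjusted over the list alone; all 13 positive, median 0.47, adjusted p = 1.56e-11), with the constitutive chaperone Hspa8 at 0.68 ± 0.10. Complement and coagulation genes fell in 10 of 25 cases (16 adjusted over the list alone; all 25 negative, median -0.27, adjusted p = 4.56e-13), with Klkb1, plasma prekallikrein, at -0.75 ± 0.12. The calls of these 3 lists held with an estimated correlation (adjusted p = 0.0322, 0.0322 and 0.0289).

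A further 6 lists passed at 8 h with the preset correlation alone. Proteasome subunits shifted up (median 0.12, adjusted p = 0.000227; 1 of 31 higher, and 1 adjusted over the list alone), as did p53 targets (0.11, adjusted p = 0.00606; 0 of 17 called, and 0 adjusted over the list alone). Fatty acid synthesis (median 0.05, adjusted p = 0.0369) had 2 higher and 1 lower of 20 (3 and 1 adjusted over the list alone), with Lpin2, a phosphatidate phosphatase, at 1.13 ± 0.14. Growth hormone and IGF genes (median -0.43, adjusted p = 0.0132; 1 of 10 lower, 3 lower and 1 higher adjusted over the list alone) and endoplasmic reticulum folding genes (-0.15, adjusted p = 0.0296; 3 of 20 lower, likewise 3 adjusted over the list alone) shifted down. The female-biased list tested up (adjusted p = 0.0295; 1 of 9 higher, 2 adjusted over the list alone) with a mean of 0.45 but a median of -0.02, since the one called member, Acot3, carried the mean. Their adjusted p with an estimated correlation was 0.532, 0.0744, 0.777, 0.178, 0.564 and 0.0989 in this order. Leaving out 1 array ended the call of the synthesis list (corn oil replicate 1 or 2 or DEHP replicate 3; adjusted p = 0.272, 0.0637 and 0.165), the folding list (corn oil replicate 1, DEHP replicate 1 or DEHP replicate 3; 0.169, 0.102 and 0.212), the growth hormone list (corn oil replicate 3; 0.139), the p53 list (DEHP replicate 2; 0.103) and the female-biased list (corn oil replicate 2; 0.058). The p53 median was 0.17 without corn oil replicate 1 and 0.02 without corn oil replicate 3, and the folding median -0.26 and -0.08 without DEHP replicate 2 or 3. The synthesis median ran from 0 without DEHP replicate 3 to 0.15 without corn oil replicate 3, and was 0.11 without DEHP replicate 2 and 0.03 without corn oil replicate 1 or DEHP replicate 1. The female-biased median ran from -0.07 (without corn oil replicate 2) to 0.10 (without corn oil replicate 3) and was 0.07, 0, 0.04 and 0.03 without corn oil replicate 1 or DEHP replicate 1, 2 or 3.

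Other settings also ended calls among these 8 h lists. Folding was lost with the mean of all probe sets (adjusted p = 0.38) and with genes above the 40th percentile (0.155), and growth hormone genes with the same settings (0.054 and 0.0721). Fatty acid synthesis was lost with quantile normalization (0.066), with the Actb covariate (0.0923) and without both corn oil 8 h replicate 2 and corn oil 72 h replicate 1 (0.0524). The female-biased list was lost with quantile normalization (0.0567) and without those 2 arrays (0.0611).

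At 8 h 752 genes were called, 232 higher and 520 lower, with 2858 at an unadjusted p under 0.05. At least 2-fold changes were 45 higher and 20 lower, and 18.6% of all genes had separated arrays, against 10% by chance. The count was 450 without corn oil replicate 2 (the array with the high Actb difference), 463 without DEHP replicate 1 and 388 without DEHP replicate 3. It was 327 with the Actb difference as a covariate and 424 from the 6 arrays of that time alone. Of 62 called genes under the naming rule, 37 stayed called in each of the 6 fits without 1 array.

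**Figure D2:**
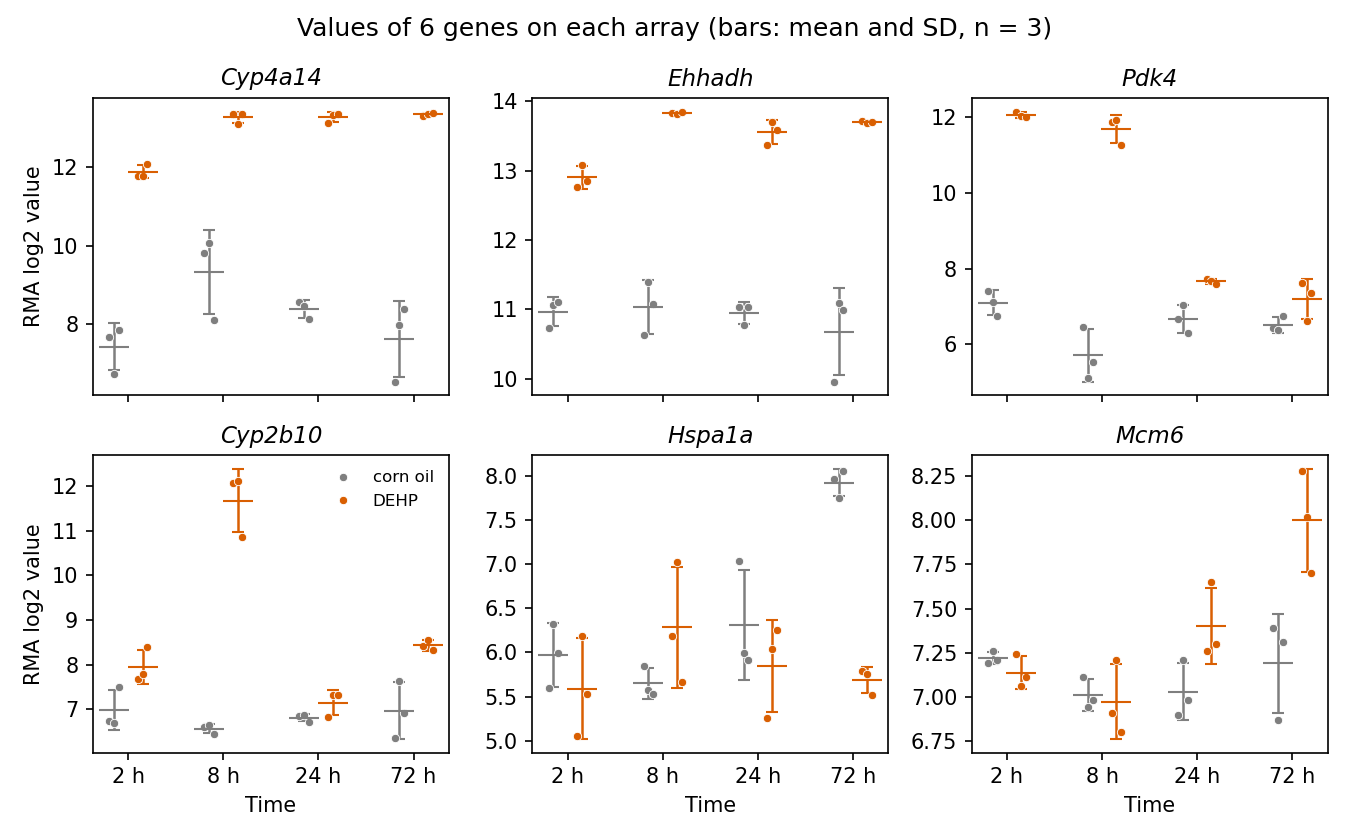
RMA log2 values (vertical axis) of 6 genes on each of the 24 arrays by time, with the mean and SD of 3 arrays per group. Cyp4a14 and Ehhadh stayed high with DEHP from 2 to 72 h, Pdk4 was high at 2 and 8 h (12.05 and 11.68), Cyp2b10 peaked at 8 h (11.68), and Hspa1a at 72 h was 5.69 with DEHP against 7.92 with corn oil.

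At 24 h the called rises included genes of fatty acid oxidation. Cyp4a14 rose by 4.86 ± 0.40 (adjusted p = 1.37e-07), Vnn1 by 3.46 ± 0.30, Acot1 by 3.07 ± 0.43, Cyp4a31, another fatty acid omega-hydroxylase, by 2.67 ± 0.19 (adjusted p = 4.62e-08) and Ehhadh by 2.61 ± 0.21. Retsat, which saturates retinol, rose by 1.75 ± 0.29 (adjusted p = 0.00431). Pdk4 at 1.00 (adjusted p = 0.212) and Cyp2b10 at 0.34 (adjusted p = 0.795) did not pass the test. Slc22a7, an organic anion transporter, fell by 1.03 ± 0.13 (adjusted p = 0.000241), and Cyp2c70, which makes mouse-specific bile acids, fell by 0.68 ± 0.12, a call lost without DEHP replicate 2 (-0.77 to -0.63 over the 6 fits).

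Mitochondrial oxidation genes rose in 9 of 21 cases at 24 h (16 adjusted over the list alone; median 0.44, adjusted p = 9.53e-32), among them Eci1 (1.11 ± 0.17) and Decr1 (0.94 ± 0.14), which process unsaturated fatty acids, and Acadl, a long-chain acyl-CoA dehydrogenase (0.77 ± 0.11). Of 9 omega-hydroxylation genes 3 rose (3 higher and 1 lower adjusted over the list alone; adjusted p = 1.74e-05). Complement and coagulation genes shifted down (median -0.25, adjusted p = 3.01e-17), with 1 of 25 called and 14 adjusted over the list alone. These 3 calls held with an estimated correlation (adjusted p = 0.0289 each). Peroxisomal oxidation genes rose in 5 of 33 cases (13 adjusted over the list alone; median 0.22, adjusted p = 2.72e-13), with Acaa1b, a peroxisomal thiolase, at 1.04 ± 0.18 and Ech1 at 0.94 ± 0.15. Proteasome subunits were all positive (31 of 31; median 0.24, adjusted p = 5.09e-17), with 1 called higher and 13 adjusted over the list alone. With an estimated correlation the adjusted p of the peroxisomal and proteasome lists was 0.0687 and 0.0989. The peroxisomal median was 0.13 without DEHP replicate 2, and the proteasome median 0.15 without corn oil replicate 1. The omega-hydroxylation median (0.07) was 0.13 and 0.15 without corn oil replicate 2 or 3 and 0.20 without DEHP replicate 3.

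Other lists called at 24 h with the preset correlation lost the call with an estimated one. Upward shifts were those of lipid uptake (median 0.10, adjusted p = 0.00332; 1 of 23 higher, and 1 adjusted over the list alone), DNA replication (0.11, adjusted p = 8.45e-05; 0 of 34 called, 0 adjusted over the list alone) and stellate cell markers (0.11, adjusted p = 0.0203; 0 of 12 called, 0 adjusted over the list alone). Heat shock genes tested up (adjusted p = 0.0296) with a mean of 0.10 and a median of -0.01; the mitochondrial chaperonins Hspe1 (0.54 ± 0.10) and Hspd1 (0.39 ± 0.08) were its 2 called members, with 3 adjusted over the list alone. The Hspe1 call was lost without DEHP replicate 2 (0.45 to 0.60 over the 6 fits) and the Hspd1 call in each of those fits (0.36 to 0.42). Acute phase genes (-0.16, adjusted p = 0.00119), bile acid genes (-0.17, adjusted p = 0.00788), clock genes (-0.15, adjusted p = 0.0041) and amino acid catabolism (-0.07, adjusted p = 0.00467) shifted down with 0 called members each. Adjusted over the list alone, acute phase and clock still had 0, bile acid 1 higher and amino acid catabolism 2 lower. In the order given, the adjusted p with an estimated correlation was 0.307, 0.181, 0.532, 0.489, 0.627, 0.317, 0.0868 and 0.393.

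Single arrays decided several of these 24 h lists. Without corn oil replicate 3 the adjusted p was 0.153 for bile acid, 0.334 for acute phase, 0.0695 for clock, 0.46 for amino acid catabolism, 0.0883 for heat shock and 0.177 for stellate markers. The heat shock median ran from -0.16 without corn oil replicate 2 to 0.15 without corn oil replicate 1 (adjusted p = 2.52e-05), and was above 0 without corn oil replicate 3 or DEHP replicate 1 or 2 (0.06, 0.06 and 0.02). Its call also ended without corn oil replicate 2 (0.755) or DEHP replicate 3 (0.328), with quantile normalization (0.105), with the mean of all probe sets (0.1) and from the 6 arrays of that time alone (0.0596), and the stellate call without DEHP replicate 2 (0.591). Without corn oil replicate 2 the medians were -0.29 for acute phase, -0.27 for clock and 0.17 for stellate markers, and without DEHP replicate 2 or 3 the stellate median was 0.03 or 0.24. Without corn oil replicate 3 the median was -0.11 for bile acid and -0.09 for acute phase. The amino acid catabolism median was -0.11, -0.13 and -0.02 without corn oil replicate 1, 2 or 3. The lipid uptake median was 0.17 without DEHP replicate 1 and 0.06 without DEHP replicate 2. The CAR and PXR list, not called at 24 h (0 of 23 called, 3 higher adjusted over the list alone; median 0.10, adjusted p = 0.0662), passed with the mean of all probe sets (adjusted p = 0.0484) and without DEHP replicate 1 (0.16, adjusted p = 0.0106).

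At 24 h 54 genes were called, 46 higher and 8 lower, with 1480 at an unadjusted p under 0.05. At least 2-fold changes were 16 higher and 2 lower, and 13.8% of all genes had separated arrays, against 10% by chance. The count was 33 without corn oil replicate 1, 97 without corn oil replicate 2, 27 without DEHP replicate 2, 35 without DEHP replicate 3 and 21 from the 6 arrays of that time alone. Of 25 called genes under the naming rule, 13 stayed called in each of the 6 fits without 1 array.

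At 72 h genes of fatty acid use were again raised. Some genes of cell division rose, and some chaperone, acute phase, complement and macrophage genes fell; as lists, all of these but complement lost the call with an estimated correlation, as given below. Cyp4a14 rose by 5.70 ± 0.40 (adjusted p = 5.97e-09), from 7.64 ± 0.97 to 13.34 ± 0.04 (mean and SD, n = 3 arrays), Acot1 by 4.02 ± 0.43 and Ehhadh by 3.02 ± 0.21. Cyp2b10 rose by 1.47 ± 0.29 (adjusted p = 0.00732). Falls were those of the acute phase protein Saa1 (-3.84 ± 0.59, adjusted p = 0.000747), the secreted mucosal peptide Tff3 (-2.72 ± 0.46) and the adipokine Serpina12 (-2.31 ± 0.20). The inducible heat shock proteins Hspa1a (-2.23 ± 0.32) and Hspa1b (-1.98 ± 0.36) and the choline kinase Chka (-1.73 ± 0.15) fell as well.

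Vnn1 (3.03 ± 0.30), Cyp4a31 (3.04 ± 0.19), Retsat (2.28 ± 0.29) and the fatty aldehyde dehydrogenase Aldh3a2 (1.88 ± 0.27) also rose at 72 h. The fatty acid transporter Cd36 rose by 2.20 ± 0.47 (adjusted p = 0.0116), a call lost without corn oil replicate 2 or 3 or DEHP replicate 2 or 3 (2.04 to 2.40 over the 6 fits). Saa2 fell by 3.95 ± 0.95, a call lost without corn oil replicate 1 or any 1 of the DEHP arrays (-4.72 to -2.68). Slc13a3, a carboxylate transporter, fell by 1.74 ± 0.40, with 1 of 4 probe sets at 0.03 and the call lost without corn oil replicate 1 or DEHP replicate 2 or 3 (-2.17 to -1.18). Pdk4 at 0.68 (adjusted p = 0.152), Ppara at 0.12 (0.799) and Ccnd1, a cyclin of G1, at -0.56 (0.132) did not pass.

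Genes of G2/M and mitosis rose in 6 of 35 cases at 72 h (16 adjusted over the list alone; 34 of 35 positive, median 0.36, adjusted p = 6.97e-14). Hmmr, a spindle protein (0.95 ± 0.21), was called, a call lost without corn oil replicate 2 or DEHP replicate 1 (0.73 to 1.15 over the 6 fits), while Mki67 at 0.46 (adjusted p = 0.239) was not. DNA replication genes rose in 6 of 34 cases (12 higher and 1 lower adjusted over the list alone; median 0.17, adjusted p = 9.13e-10), with Mcm6 (0.81 ± 0.15) of the replicative helicase and the primase Prim1 (0.63 ± 0.12). Under the estimated correlation the adjusted p was 0.158 for mitosis and 0.0582 for replication. The mitosis median was 0.17 without DEHP replicate 1, whose list mean of 0.79 compares with 0.18 and 0.07 on the other DEHP arrays, and the replication median was 0.26 without DEHP replicate 3. That DEHP replicate 1 also had the raised pancreas markers. The mitosis list means on the corn oil 72 h arrays were -0.06, -0.17 and 0.04. The mitosis members Birc5 (1.30), Ccnb2 (0.79) and Mad2l1 (0.63) stayed called in 3, 2 and 3 of the 6 fits without 1 array.

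Among oxidation lists at 72 h, 3 of 9 omega-hydroxylation genes rose (4 higher and 1 lower adjusted over the list alone; adjusted p = 3.26e-05, and 0.0289 with an estimated correlation). Mitochondrial oxidation had 9 of 21 higher (15 adjusted over the list alone; median 0.37, adjusted p = 1.24e-18), with the dehydrogenase Acadm at 0.88 ± 0.10, and peroxisomal oxidation 8 of 33 (13 adjusted over the list alone; median 0.21, adjusted p = 2.5e-10), with Acaa1b at 1.33 ± 0.18. Lipid uptake had 5 of 23 higher (8 higher and 1 lower adjusted over the list alone; median 0.13, adjusted p = 2.7e-05). Drug-metabolism genes of CAR and PXR had 5 of 23 (7 adjusted over the list alone; median 0.17, adjusted p = 1.28e-05), with the carboxylesterase Ces2a at 0.93 ± 0.19. With an estimated correlation the adjusted p of these 4 lists was 0.0608, 0.0989, 0.131 and 0.131. Without corn oil replicate 1 the peroxisomal median was 0.13 and the lipid uptake median 0.06, and the latter was 0.22 without corn oil replicate 2 or 3.

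Complement and coagulation genes fell in 11 of 25 cases at 72 h (21 adjusted over the list alone; all 25 negative, median -0.33, adjusted p = 2.31e-15, and 0.0289 with an estimated correlation), including C8b (-0.86 ± 0.11) and C9 (-0.81 ± 0.12) of the membrane attack complex. Heat shock genes fell in 8 of 13 cases (9 lower and 2 higher adjusted over the list alone; median -0.71, adjusted p = 1.92e-07), with the co-chaperones Dnajb1 (-1.62 ± 0.26) and Hsph1 (-1.54 ± 0.21). Endoplasmic reticulum folding genes fell in 9 of 20 cases (17 lower and 1 higher adjusted over the list alone; median -0.58, adjusted p = 5.27e-10), with Herpud1 of protein degradation (-0.74 ± 0.14), the stress factor Ddit3 (-0.74 ± 0.14) and Xbp1, a transcription factor of the unfolded protein response (-0.70 ± 0.14). The adjusted p with an estimated correlation was 0.0823 for heat shock and 0.0719 for folding.

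Acute phase genes fell in 4 of 25 cases at 72 h (10 adjusted over the list alone; all 25 negative, median -0.48, adjusted p = 1.4e-07). Macrophage markers fell in 6 of 14 cases (13 adjusted over the list alone; all 14 negative, median -0.68, adjusted p = 2.01e-08), with C1qc (-0.86 ± 0.24), a complement subunit that Kupffer cells make, a call lost in each of the 6 fits without 1 array (-1.01 to -0.72). The calls of the members C1qa (-0.79), Cd163 (-0.87) and Cd5l (-0.90) held in 0, 1 and 1 of those fits (-0.92 to -0.67, -1.16 to -0.67 and -1.07 to -0.68). Endothelial markers shifted down (median -0.40, adjusted p = 0.000647; 0 of 12 called, 4 lower adjusted over the list alone). With an estimated correlation the adjusted p was 0.346, 0.225 and 0.475. Corn oil 72 h replicate 1 had high acute phase, immediate-early, neutrophil and pancreas genes. Without it the acute phase median was -0.34 (adjusted p = 0.0104), and -0.74 and -0.73 without corn oil replicate 2 or 3. The list means of macrophage markers were 0.52, 0.07 and 0.42 on the corn oil arrays and -0.43, -0.39 and -0.13 on the DEHP arrays.

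**Figure D3:**
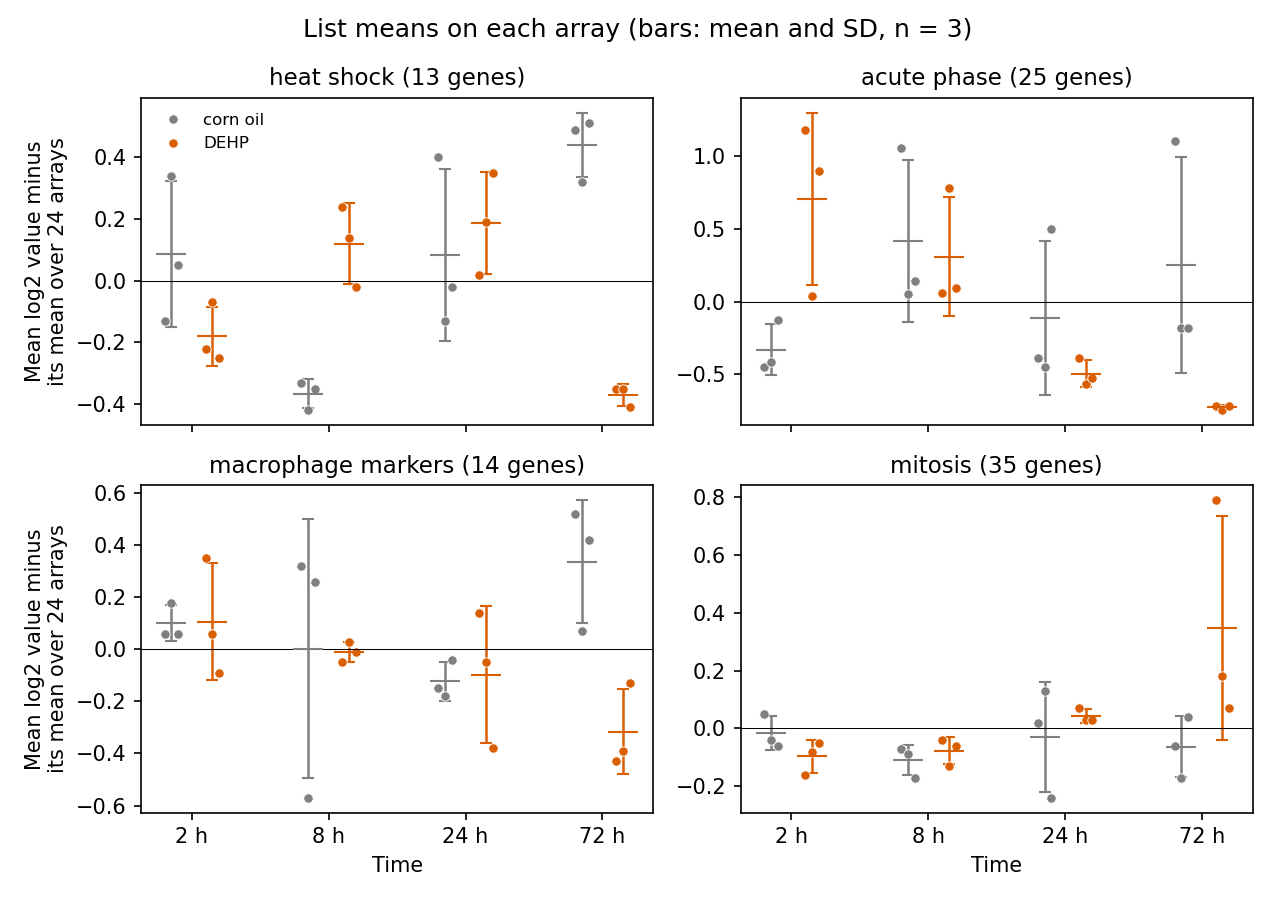
Mean log2 value of 4 gene lists on each array minus its mean over 24 arrays (vertical axis) by time, with the mean and SD of 3 arrays per group. At 72 h the heat shock means lay between -0.41 and -0.35 with DEHP and between 0.32 and 0.51 with corn oil, and DEHP replicate 1 had the highest mitosis mean (0.79).

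At 72 h 760 genes were called, 205 higher and 555 lower, with 3930 at an unadjusted p under 0.05. At least 2-fold changes were 31 higher and 29 lower, and 28.2% of all genes had separated arrays, against 10% by chance. The share of higher genes was 27% and became 50.9% of 566 genes with quantile normalization, so the excess of lower genes depended on the scaling. The count was 248 without corn oil replicate 2, 321 without corn oil replicate 3, 254 without DEHP replicate 2, 247 without DEHP replicate 3 and 2749 with array weights. Of 71 called genes under the naming rule, 38 stayed called in each of the 6 fits without 1 array.

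**Figure D4:**
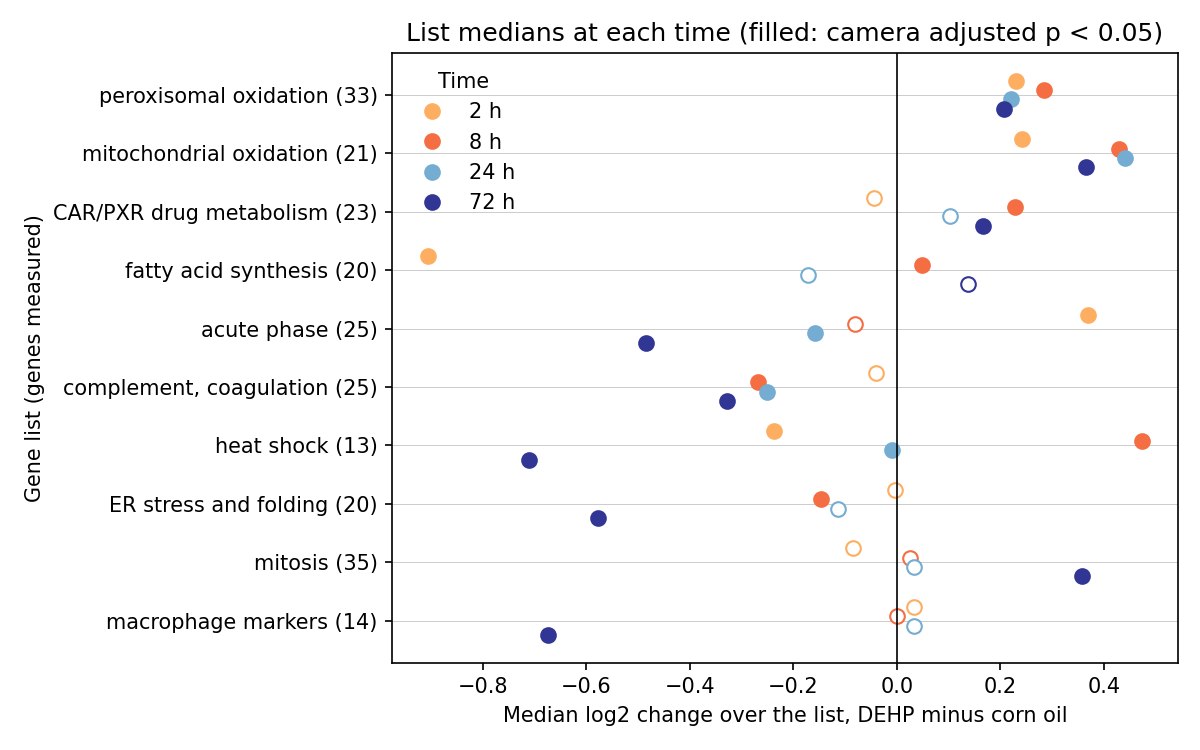
Median log2 change between DEHP and corn oil (horizontal axis) of 10 gene lists at the 4 times, with the number of genes measured in brackets and filled points where the camera test with the preset correlation gave an adjusted p under 0.05. Both oxidation lists were positive at all 4 times, while the heat shock median was 0.47 at 8 h and -0.71 at 72 h.

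Some lists were not called at any time but held called genes, where 4.13% of all genes were called at 8 h and 4.18% at 72 h. Antioxidant genes (22 measured) had 2 higher at 8 h, with Srxn1, which repairs peroxiredoxins, at 1.12 ± 0.13. At 72 h they had 2 higher and 2 lower, with the glutathione transferase Gsta2 at 1.75 ± 0.37 and the haem oxygenase Hmox1 at -0.67 ± 0.15 (lowest adjusted p of the list over the 4 times 0.0734). Glucose genes (14) had 1 higher at 2 h, 3 lower at 8 h and 1 lower at 72 h (lowest adjusted p = 0.151), and apoptosis genes (16) 1 higher at 2 h and 3 lower at 8 h (0.0583). Male-biased genes (10) had 2 lower at 8 h (0.074), interferon genes (17) 1 lower at 8 h (0.33), bile duct markers (6) 1 higher at 72 h, the keratin Krt23 at 1.10 ± 0.13 (0.112). Immediate-early genes (19) had 1 higher at 2 h and 1 lower at 8 h (0.0583), and their median was -0.34 at 72 h. Their list means at 72 h were 1.31, -0.29 and 0.05 on the corn oil arrays and -0.10, -0.30 and -0.20 on the DEHP arrays, so corn oil replicate 1 carried most of that difference. No member of the lymphocyte (11 measured), neutrophil (8), red blood cell (3), exocrine pancreas (9) or adipocyte (5) markers was called at any time, and the lowest adjusted p of these lists was 0.334, 0.502, 0.514, 0.728 and 0.154.

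Across times, 7 genes were higher at all 4 and 0 were lower at all 4. These were Acot1, Acot2, Cyp4a14, Cyp4a31, Ehhadh, Vnn1 and Hsdl2, a peroxisomal dehydrogenase-like protein named here after its values were seen (1.01, 1.36, 0.88 and 0.63 in time order, SE 0.14). The 2 h call of Acot2 (1.01 ± 0.24) was lost in each of the 6 fits without 1 array (0.97 to 1.05). Of 1502 genes called at any time, 1323 were called at 1 time alone and 179 at 2 or more. Calls shared between 2 and 8 h were 52 higher, where 1.43 were expected for independent lists (Fisher's exact test, two-sided p = 1.11e-69), and 4 lower against 1.11. Between 24 and 72 h 35 higher genes were shared against 0.518 expected (Fisher's exact test, p = 3.73e-60), and 5 lower against 0.244. Between 8 and 72 h 35 higher (2.61 expected) and 50 lower genes (15.9 expected) were shared, while 7 genes went from higher to lower and 4 from lower to higher. Between 2 and 72 h 8 higher genes were shared (1.26 expected) and 8 went from higher to lower. All 4 comparisons used the same residual spread of each gene, so genes with a small spread are called more easily at several times. The expected counts and the p-values of Fisher's test take no account of this or of genes that vary together. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.314 between 2 and 8 h, 0.479 between 24 and 72 h and -0.099 between 2 and 72 h.

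The effect of DEHP itself differed between times for named genes. From 2 to 8 h the effect on Cyp2b10 grew by 4.16 ± 0.41 (adjusted p = 1.88e-05), and that on Hsd3b5 changed by -1.49 ± 0.25 and on Apol7a by -1.42 ± 0.17. From 8 to 24 h the effect on Pdk4 changed by -4.98 ± 0.39 (adjusted p = 1.59e-07), on Cyp2b10 by -4.79 ± 0.41, on Acot3 by -2.86 ± 0.49, on Rab30 by -2.22 ± 0.36 and on St3gal5, which makes the ganglioside GM3, by -1.88 ± 0.26. In the same interval the effects on Ppp1r3c (2.67 ± 0.36), Hsd3b5 (1.75 ± 0.25) and Apol7a (1.53 ± 0.17) turned upward. From 24 to 72 h the effect changed downward for all 4 called genes: the stress kinase Sgk1 (-1.81 ± 0.24), Chka (-1.78 ± 0.22), the vasopressin receptor Avpr1a (-1.02 ± 0.18) and Bpgm, an enzyme of red cell metabolism (-0.73 ± 0.13). Bpgm itself rose by 0.64 in corn oil over that interval, which makes up most of its change. Sgk1 and Chka were called in each of the 12 fits without 1 array, Avpr1a in 2 and Bpgm in 3. Chka also changed by -2.04 in corn oil from 2 to 8 h. Whether a different phase of the daily clock in the 72 h groups moved Chka was not tested.

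Heat shock was the only list called between times with an estimated correlation. Their effect rose from 2 to 8 h (median 0.74; all 13 positive, 2 called and 12 adjusted over the list alone) and fell from 24 to 72 h (-0.77; all 13 negative, 0 called and 10 adjusted over the list alone) and from 8 to 72 h (-1.21; 9 of 13 called lower and 10 adjusted over the list alone). The adjusted p of these 3 calls with an estimated correlation was 0.0375, 0.0375 and 0.0372. From 2 to 8 h the list fell in corn oil while its DEHP effect rose (median -0.51, adjusted p = 2.11e-08, all 13 negative). That fall had an adjusted p of 0.309 with an estimated correlation. On the DEHP arrays the list means were -0.22, -0.07 and -0.25 at 2 h and 0.24, 0.14 and -0.02 at 8 h. From 24 to 72 h the heat shock list rose in corn oil while its DEHP effect fell (median 0.17, adjusted p = 0.0021; all 13 positive, 0 called and 2 adjusted over the list alone). The adjusted p of that rise with an estimated correlation was 0.663, and leaving out corn oil 24 h replicate 2 ended its call (0.06, adjusted p = 0.258). Its median was 0.33 without corn oil 24 h replicate 1 and 0.09 without corn oil 72 h replicate 3. The effect on fatty acid synthesis shifted up from 2 to 8 h (median 0.88, adjusted p = 2.08e-11, with 2 of 20 higher and 7 adjusted over the list alone). Its adjusted p with an estimated correlation was 0.304. In corn oil this list fell over the same interval (median -0.75, camera adjusted p = 1.67e-10, and 0.536 with an estimated correlation). On the DEHP arrays its list means were -0.46, 0.32 and -0.26 at 2 h and -0.05, -0.15 and 0.08 at 8 h. Mitosis genes shifted up from 24 to 72 h (0.32, adjusted p = 1.26e-09; 0 of 35 called and 0 adjusted over the list alone) and macrophage markers down (-0.70, adjusted p = 1.88e-09; 0 of 14 called and 9 adjusted over the list alone). Endothelial (-0.48, adjusted p = 5.52e-05) and stellate cell markers (-0.24, adjusted p = 0.00521) went down with them, with all 12 members of each negative and 0 called over all genes or over the list alone. Their adjusted p with an estimated correlation was 0.517 for mitosis, 0.492 for macrophage, 0.582 for endothelial and 0.603 for stellate markers. In corn oil the macrophage, endothelial and stellate lists rose from 24 to 72 h (medians 0.49, 0.33 and 0.25). That rise makes up most of the change in the DEHP effect on these markers. With the preset correlation 16, 7 and 15 of 37 lists were called for the 3 successive intervals, and 1, 0 and 1 with an estimated one.

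A DEHP effect at any time was called in 1176 genes and an effect that differed between times in 378 (unadjusted p under 0.05 in 4014 and 2758). The second count was 241 without corn oil 2 h replicate 1, 242 without DEHP 72 h replicate 2 and 229 without DEHP 72 h replicate 3. Between 2 and 8 h 76 genes differed, 26 upward and 50 downward (1833 at an unadjusted p under 0.05). This count was 31 and 42 without corn oil 2 h replicate 1 or corn oil 8 h replicate 2, 35 and 37 without DEHP 2 h replicate 1 or 3, and 28, 181 and 37 without DEHP 8 h replicate 1, 2 or 3. Between 8 and 24 h 85 differed, 52 upward and 33 downward (1683 unadjusted). It was 54 without corn oil 8 h replicate 2, 50 and 48 without DEHP 8 h replicate 1 or 3, 42 without corn oil 24 h replicate 1, and 45 and 51 without DEHP 24 h replicate 1 or 2. Between 24 and 72 h the 4 genes (1393 unadjusted) became 18 without corn oil 72 h replicate 1 and 2 without any 1 of the DEHP 24 h arrays, any 1 of the DEHP 72 h arrays or corn oil 72 h replicate 2. A call at 1 time and not at another is a difference between times only for the genes counted here.

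In corn oil alone, genes of the daily clock were among those that changed. From 2 to 8 h the clock outputs Dbp (3.37 ± 0.57), Usp2 (1.81 ± 0.19), Per3 (1.38 ± 0.18) and Wee1 (1.09 ± 0.17) rose, and Arntl, the core clock activator, fell by 1.27 ± 0.20 (adjusted p = 0.000596). Falls included the tubulin gene Tubb2a (-2.48 ± 0.23), the water channel Aqp8 (-2.06 ± 0.28), Chka (-2.04 ± 0.15) and Acly (-1.75 ± 0.34), of whose 6 probe sets 1 was at 0.01. Of 21 clock genes 11 rose and 4 fell (12 and 5 adjusted over the list alone; median 0.40, adjusted p = 0.000702). Peroxisomal oxidation rose in 9 of 33 cases (15 and 1 lower adjusted over the list alone; median 0.26, adjusted p = 2.11e-08), and the synthesis lists of fatty acids (8 of 20 lower, 13 adjusted over the list alone; -0.75, adjusted p = 1.67e-10) and cholesterol (6 of 20 lower, 10 adjusted over the list alone; -0.37, adjusted p = 1.73e-08) went down. Heat shock genes fell in 5 of 13 cases (6 adjusted over the list alone; -0.51, adjusted p = 2.11e-08). With an estimated correlation the adjusted p of these 5 lists was 0.309, 0.536, 0.536, 0.585 and 0.309. Their preset calls held in every fit without 1 array.

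Markers of other cells also went down in corn oil from 2 to 8 h. Endothelial markers (median -0.21, adjusted p = 0.00117) were negative in 12 of 12 cases, with 0 called and 2 adjusted over the list alone. Stellate cell markers (-0.23, adjusted p = 0.00107; 11 of 12 negative) and pancreas markers (-0.995, adjusted p = 0.0187; 9 of 9 negative) had 0 called over all genes or over the list alone. Their adjusted p with an estimated correlation was 0.723, 0.663 and 0.876. The endothelial call was lost without corn oil 8 h replicate 2, the array with the Actb difference of 1.46 (-0.03, adjusted p = 0.522), and the median was -0.44 without corn oil 8 h replicate 3. The stellate call was lost without corn oil 8 h replicate 1 (-0.14, adjusted p = 0.0769; -0.40 without replicate 3). The pancreas call was lost without corn oil 2 h replicate 2 (-0.48, adjusted p = 0.276) or corn oil 8 h replicate 3 (-0.89, adjusted p = 0.0897), and its median was -1.62 without corn oil 2 h replicate 3. In this comparison 14 of 37 lists were called with the preset correlation and 0 with an estimated one.

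From 2 to 8 h in corn oil 738 genes were called, 539 higher and 199 lower. Between 2 and 24 h, 2 genes were called (Hsd3b2 0.69 ± 0.11 and Lpin2 -0.87 ± 0.14; 1396 at an unadjusted p under 0.05), both of which lost the call in 5 of the 6 fits without 1 array. With the preset correlation 15 of 37 lists were called over that interval, and 0 with an estimated one. Fatty acid synthesis was lower at 24 h than at 2 h (median -0.73, adjusted p = 1.19e-10; 18 of 20 negative, 1 called and 12 adjusted over the list alone; adjusted p = 0.536 with an estimated correlation), a preset call that held in all 6 fits without 1 array (-0.93 to -0.54). Corn oil 2 h was thus higher for this list than both corn oil 8 h (0.75) and 24 h, and the DEHP fall at 2 h was measured against that level. Stellate cell (-0.26, adjusted p = 1.55e-05; 5 of 12 lower adjusted over the list alone), endothelial (-0.29, adjusted p = 0.00107) and pancreas markers (-1.33, adjusted p = 0.00117; 0 adjusted over the list alone in both) were lower too, with 0 called and an adjusted p of 0.555, 0.723 and 0.723 with an estimated correlation. The endothelial call was lost without corn oil 24 h replicate 2 (-0.21, adjusted p = 0.154) and the pancreas call without corn oil 2 h replicate 2 (-0.67, adjusted p = 0.113).

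Between 24 and 72 h in corn oil 2 genes were called, Ccn2, a matrix growth factor (1.32 ± 0.19), and Bpgm (0.64 ± 0.09; 1579 unadjusted), both lost without corn oil 24 h replicate 1, while the macrophage markers shifted up as a list (median 0.49, adjusted p = 2.22e-07; 0 of 14 called and 3 adjusted over the list alone). Endothelial (0.33, adjusted p = 2.9e-05) and stellate cell markers (0.25, adjusted p = 0.00402) shifted up with them, with all 12 members of each positive and 0 called over all genes or over the list alone. The adjusted p of these 3 lists with an estimated correlation was 0.63, 0.682 and 0.723. Leaving out corn oil 24 h replicate 3 (0.21, adjusted p = 0.156) or corn oil 72 h replicate 3 (0.16, adjusted p = 0.0747) ended the stellate call. Any difference between the 4 corn oil times was called in 646 genes (3033 unadjusted). That count was 417 without the 2 h replicate 1, 309 without the 8 h replicate 2, 402 without both that array and the 72 h replicate 1, and 181 with the Actb difference as a covariate.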

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

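The comparisons with other groupings were tests chosen in advance; the RNA quality and pancreas covariates were added after the data were seen but before their own outcome was known, and the comparisons with corn oil 24 h, the clock slope, the test of 1 responding array and the test of non-parenchymal markers were chosen only after the result was seen. Heat shock genes stood out first, because the effect of DEHP on them differed between times. The list median of that difference was 0.74 from 2 to 8 h and -0.77 from 24 to 72 h, with all 13 members in that direction both times. In corn oil the list itself shifted the other way over both intervals (medians -0.51 and 0.17). Neither corn oil shift was called with an estimated correlation (adjusted p = 0.309 and 0.663). The effect of DEHP differed between times in 378 genes, in 76 between 2 and 8 h, in 85 between 8 and 24 h and in 4 between 24 and 72 h. Probe sets without a single gene, which the gene counts leave out, were also called, with 24, 86, 12 and 37 of 10092 at 2, 8, 24 and 72 h (51 control probe sets of the array left out), and the sequences behind them were not examined.

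At 72 h, heat shock genes (median -0.71) and endoplasmic reticulum folding genes (-0.58) were lower with DEHP, though with an estimated correlation neither list was called (adjusted p = 0.0823 and 0.0719). A high level in the 72 h corn oil arrays was argued against as the whole cause, since the medians against corn oil 24 h were -0.48 (9 of 13 lower, adjusted p = 6.62e-05, unadjusted p = 0.0441 with an estimated correlation) and -0.68 (18 of 20 lower, adjusted p = 3.75e-15, unadjusted p = 0.00179 with an estimated correlation). With the Actb difference as a covariate the medians were -0.71 (adjusted p = 1.96e-07) and -0.55 (adjusted p = 8.21e-10). This cannot decide on RNA quality, since the Actb difference varied little at 72 h and was largest on an 8 h array (1.46). At 72 h it lay between 0.54 and 0.61 on the corn oil arrays and between 0.64 and 0.67 on the DEHP arrays, so it separated the groups. A different phase of the daily clock in the 72 h groups stays open: over 21 clock genes the 72 h effect had a slope of 0.41 ± 0.10 on the corn oil difference between 8 and 2 h, which times the corn oil medians of the lists gives -0.21 for heat shock and -0.07 for folding, and the sampling hour is not in the labels. These products are smaller than the falls of -0.71 and -0.58. They assume that the lists follow the clock genes in proportion, so they set no upper limit on the part of a clock shift. The heat shock means on the DEHP 72 h arrays (-0.35, -0.35 and -0.41) lay close to those of corn oil 8 h (-0.33, -0.42 and -0.35). For folding these means were -0.26, -0.32 and -0.33 against -0.08, -0.28 and -0.21. Of the 21 clock genes, 2 were called higher and 3 lower with DEHP at 72 h. A lowered chaperone expression with DEHP at 72 h may be the biological explanation, as a hypothesis. How much of each fall a shift of the clock or RNA quality adds could not be told apart from it.

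Acute phase genes were higher with DEHP at 2 h (median 0.37) and lower at 72 h (-0.48), though with an estimated correlation neither list was called (adjusted p = 0.107 and 0.346). A single strongly responding array was argued against as the whole cause, since the median nearest to 0 was 0.31 at 2 h (without DEHP replicate 1, adjusted p = 3.54e-10) and -0.34 at 72 h (without corn oil replicate 1, adjusted p = 0.0104). With the mean of the pancreas markers as a covariate the medians were 0.36 (adjusted p = 4.5e-18) and -0.48 (adjusted p = 1.3e-08). This covariate could hardly move them, since the mean of the markers differed between DEHP and corn oil by only 0.05 at 2 h and -0.07 at 72 h. The 2 groups thus carried similar marker means at both times, and an effect of pancreas tissue on single arrays was not decided. An acute phase response that differs between single mice for reasons of handling stays open and was not tested, and it could account for a list mean of 0.04 on DEHP 2 h replicate 2 beside 1.18 and 0.90 on the others. In corn oil alone the list also rose from 2 to 8 h (median 0.31, 21 of 25 positive, camera adjusted p = 0.00107, and 0.855 with an estimated correlation). The corn oil 8 h list means were 1.06, 0.05 and 0.14, so 1 array without DEHP also reached a high level. At 8 h the DEHP effect had a median of -0.08 (camera adjusted p = 0.553). A response of the liver to DEHP may be the biological explanation at 2 h, as a hypothesis. For the values below corn oil at 72 h (25 of 25 negative), and at 24 h (median -0.16, 24 of 25), no biological explanation was tested.

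Macrophage markers were lower with DEHP at 72 h (median -0.68, adjusted p = 0.225 with an estimated correlation and so no longer called), a list of 14 genes of which 0 belong to another list and 12 lay above the median gene in corn oil (7.26); its most abundant members were Csf1r (10.47 in corn oil, -0.58, adjusted p = 0.0502), Cd5l (10.41, -0.90, called in 1 of 6 fits without 1 array) and C1qa (9.86, -0.79, called in 0 of 6). A smaller share of all non-parenchymal cells by the same factor was argued against, since the macrophage mean minus the mean of other markers differed by -0.62 (95% interval -1.05 to -0.18), with the 11 stellate cell, bile duct and lymphocyte markers above the median gene in corn oil at -0.04 (-0.27 to 0.19). Against the 8 such stellate markers alone the difference was -0.50 (-0.95 to -0.04) and against 8 endothelial markers -0.29 (-0.56 to -0.02), but endothelial markers shifted down too (list median -0.40), so a joint but unequal loss of macrophage, endothelial and stellate signal stays open. A high level in the 72 h corn oil arrays also stays open, since against corn oil 24 h the median was only -0.16 (13 of 14 lower, adjusted p = 0.0435, unadjusted p = 0.44 with an estimated correlation) and corn oil 72 h lay 0.49 above corn oil 24 h. Fewer or less active Kupffer cells may be the biological explanation, but it cannot be told apart from a high corn oil group.

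Whether other groupings of the arrays give as many genes was counted for each comparison. For the 4 times, 10 splits of 6 arrays are too few to give a share under 0.05; the real count was the highest in 1 of 10 each, with 151 genes at 2 h against 1 for the highest other split, 752 at 8 h against 1, 54 at 24 h against 1 and 760 at 72 h against 0. For an effect at any time the real count was the highest of 100 groupings (1176 genes against 463 for the highest other). The same held for a difference between times (378 against 203) and for differences between times in corn oil (646 against 256). A share of 1 in 100 makes chance unlikely for these counts but does not exclude it. Chance was not made unlikely for the successive times. There 9, 7 and 7 of 100 relabellings gave as many genes as the real 76, 85 and 4, with 696, 357 and 580 for the highest others. Such counts, several times the real one, point to a structure of the samples: 6 of the 8, 6 of the 6 and 6 of the 6 other relabellings with as many genes kept the real groups of 1 of the times whole, so that they carry the DEHP effect itself, and those that mixed both times gave at most 204, 2 and 2.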

How the results depend on the processing

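The Actb covariate, the pancreas covariate, leaving out both doubted arrays (corn oil 8 h replicate 2 and corn oil 72 h replicate 1), and quantile normalization of the lists were alternatives chosen after seeing the data; the others were planned. No named gene and no list called between DEHP and corn oil changed the direction of its test under any alternative run, but 7 tests of lists not called before became called the other way: macrophage and endothelial markers at 8 h (medians 0 and 0.04) with the Actb covariate (-0.30 and -0.21), without both doubted arrays (-0.33 and -0.21) and without corn oil 8 h replicate 2 (-0.33 and -0.21), and pancreas markers at 2 h (0.10) without DEHP 2 h replicate 1 (-1.27). Over all fits without 1 array these medians ran from -0.33 to 0.19, -0.21 to 0.22 and -1.27 to 0.85. Medians near 0 also changed sign without single arrays, for the called female-biased list at 8 h (-0.07 to 0.10) and heat shock at 24 h (-0.16 to 0.15). Lists between corn oil times are not covered by this statement on direction. Among them the immediate-early rise from 24 to 72 h (median 0.44, adjusted p = 0.0362) rested on 1 array. Its list means were 1.31, -0.29 and 0.05 at 72 h against -0.19, -0.14 and 0 at 24 h. Of 274 counts of genes under alternatives 195 stayed within 1.5 times and 79 moved, and of 21 overlaps 16 stayed and 5 moved. Of 384 tests of the main lists 364 kept their side of the threshold, 14 lost and 6 gained the call. Other called lists kept it in 509 of 576 tests and uncalled ones stayed so in 1339 of 1408, with 62 calls gained in the same direction. Named called genes kept their call in 2244 of 2835 tests, uncalled ones stayed so in 1311 of 1331. Signal over background limits dim genes, and 3 arrays per group limit each count. Where no reason is given below, the cause was not tested.

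An adjusted p under 0.01 lowers counts by construction: 62 genes at 2 h, 346 at 8 h, 29 at 24 h, 176 at 72 h, 476 at any time, 119 with a difference between times, 20, 30 and 2 for the successive times and 239 in corn oil; the overlaps became 29 (2 and 8 h, of 56), 5 (2 and 72 h, of 10), 19 (8 and 24 h, of 34), 30 (8 and 72 h, of 85) and 23 (24 and 72 h, of 40). The 1.5-fold threshold also removes genes by construction: 304 at 8 h, 260 at 72 h, 540 at any time and 318 in corn oil. With only the 6 arrays of a time, which leaves fewer degrees of freedom, 95 were called at 2 h, 424 at 8 h and 21 at 24 h. Array weights gave 2749 at 72 h (758 shared with the 760), 2549 at any time, 890 with a difference between times and 140, 266 and 140 for the successive times. The Actb covariate gave 327 at 8 h, 224 with a difference between times, 40 (2 to 8 h), 41 (8 to 24 h) and 181 in corn oil. Without both doubted arrays there were 489 at 8 h, 17 between 24 and 72 h and 402 in corn oil. Without both arrays numbered RC14 there were 184 between 2 and 8 h and 2 between 24 and 72 h. Quantile normalization gave 134 between 8 and 24 h and 2 between 24 and 72 h, and the mean of all probe sets 1 there. At 72 h quantile normalization called 566 genes (451 shared), 50.9% higher, against 27% before, and median centring 655, 28.7% higher.

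Leaving out each array in turn gave 65 to 239 genes at 2 h, 388 to 796 at 8 h, 27 to 97 at 24 h, 247 to 1095 at 72 h, 842 to 1438 at any time, 229 to 499 with a difference between times, 28 to 181, 42 to 113 and 2 to 18 for the successive times and 309 to 948 in corn oil.

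The DNA replication list at 2 h was no longer called with the mean of all probe sets (-0.04), with genes above the 40th percentile (-0.07) or with an estimated correlation (-0.08). Drug-metabolism genes of CAR and PXR at 24 h became called with the mean of all probe sets (0.10) and without both doubted arrays (0.10), and their median ran from 0.07 to 0.16 without single arrays, with the call gained in 1 of 6 fits (without DEHP replicate 1). Mitosis genes at 24 h (median 0.03) ran from -0.05 to 0.12, with the call gained in 3 of 6 fits. An estimated correlation leaves medians as they are and allows for genes that vary together; with it the call was lost for peroxisomal oxidation at 2 h (0.23), 24 h (0.22) and 72 h (0.21), mitochondrial oxidation at 2 h (0.24), 8 h (0.43) and 72 h (0.37), omega-hydroxylation at 2 h (0.09), DNA replication at 24 h (0.11) and 72 h (0.17), drug-metabolism genes at 72 h (0.17) and mitosis at 72 h (0.36).

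The replicate numbers do not pair arrays: 1 of 12 same-numbered pairs correlated above 0.1 in their deviations from the group means (-0.351 to 0.144), and 7 of 24 arrays correlated best with their own number. With the replicate block 2 genes differed between 24 and 72 h, while the other counts stayed within 1.5 times.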

Other observations

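On the first principal component the DEHP 8 h group stood apart from all other arrays. The first 4 principal components held 18.7%, 16%, 11.4% and 7.51% of the variance, and the 3 DEHP 8 h arrays had the highest scores on the first (23.5 to 26.7, with 12.1 for the next array). Exocrine pancreas markers were high on single arrays of both compounds, at 3.30, 2.05, 1.81, 1.47 and 0.91 above the mean over all arrays on DEHP 2 h replicate 1, corn oil 72 h replicate 1, corn oil 2 h replicate 2, DEHP 72 h replicate 1 and corn oil 2 h replicate 1. The most abundant of the 9 measured markers, Cela1, had a corn oil level of 10.6.

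Corn oil 8 h replicate 2 had, beside its Actb difference of 1.46 and its 18S signal of 12.35, the highest Gapdh 3' minus 5' difference (0.63) and the lowest means of macrophage (-0.57) and endothelial markers (-0.64). The array weights of limma ran from 0.42 for corn oil 24 h replicate 3 to 2.32 for DEHP 24 h replicate 1.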
